A study of Mus musculus with 8 samples.

How the data were processed

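ChIP with an antibody against H3K27ac, ChIP with IgG, and input DNA were sequenced from stimulated mouse CD8+ T cells treated with EnPGC-1 or DMSO. Samples were assigned to groups by the treatment and antibody given in the labels. Per the submitters' processing notes, the tools named were Trimmomatic 0.38, Bowtie 1.1.2, Picard 0.118, MACS2 2.2.2.20160309 and ChIPseeker 11.16.1, and the build was mm10. The parameters, the control used for peak calling, and whether the H3K27ac samples of a treatment were pooled or 1 was chosen are not given in the sources used here. Nothing in them says that replicates came from separate animals or cultures. Each treatment has 1 deposited list of peaks, without a header, giving chromosome, start, end, name and a score. No per-sample values or read depths were used here, so differences in depth, enrichment or control between treatments can change the number and width of peaks.

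The deposited score was read as the −log10 of a q-value from the peak caller. This unit is inferred from the values: the lowest scores were 1.31 in both lists, and -log10 of 0.05 is 1.30. It was used only to rank and filter peaks within 1 list. Entries of the lists that repeat 1 interval with several summits were combined into 1 interval with the highest of their scores, which turned 84538 DMSO entries into 81522 intervals and 329623 EnPGC-1 entries into 253423. Both lists held 20 chromosomes, 1 to 19 and X. Coordinates are printed 1-based.

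Genes came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10, with 21883 protein-coding genes. The table used gives no strand, so the planned window around the transcription start became a window around either gene end. This deviates from the plan, can count intervals at the 3' end, and holds for every statement on gene ends. Covered bases within 5 kb were taken at the gene end with more bases covered by both lists together. The 22 gene lists had 638 entries that matched a gene and 2 that did not. The lists were the PGC-1 network, oxidative phosphorylation, fatty acid oxidation, the TCA cycle, mitochondrial dynamics, glycolysis, T cell identity, T cell activation, CD8 effector, CD8 memory, exhaustion, histone acetylation, cell cycle, apoptosis and stress, B cell, myeloid, CD4/Treg/NK, erythroid and platelet, liver, neuronal, muscle and testis genes. Ribosomal protein, olfactory and vomeronasal receptor genes were added after the values were seen, as was the pooling of lists. The 1501 olfactory, vomeronasal and taste receptor genes are rarely marked and lower the share in random lists.

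Overlap required 1 bp and was set beside 20 random placements of the other list within chromosomes, and beside local shifts of 10 to 50 kb, which were added later. Shares have exact Clopper-Pearson intervals at 95%. For each gene list, the share of members without a DMSO interval that had an EnPGC-1 interval was placed among 10000 random lists of such genes. The median difference in covered bases was placed among 10000 random lists matched on 10 strata of mean covered bases. That mean is taken over both lists, so matching on it removes part of any gain. Percentiles describe these lists and are not p-values. The random draws were reassigned once after first results had been seen, so that all calculations shared the same draws, and this moved oxidative phosphorylation from below to above percentile 2.5 in covered bases. Both an exact percentile for shares and 100000 random lists for covered bases were then added to settle such limits. Domains were intervals joined within 12.5 kb and ranked by covered bases.

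Gene lists, tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added. The rule named Ppargc1a and Ppargc1b, and of each list up to 2 members with the largest difference in covered bases and 1 with the most negative. It also named the 10 highest-scoring intervals found in 1 list alone and the genes at the 10 leading domains. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen. Alternatives were a stricter score, equal numbers of highest-scoring intervals, merging within 1000 bp, leaving out intervals under 500 bp or chromosome X, other overlap rules, windows of 500 bp, 2500 bp and 10 kb, unmatched random lists, and joining within 5000 bp. Added later were the count of deposited entries, random lists without receptor genes or matched on EnPGC-1 coverage within 250 kb, whole genes with 10 kb on each side, and both ways of settling limits.

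The calculations were tested on simulated data. Covered bases differed from a base-by-base count in 0 of 200 simulated lists, and a planted overlap of 70% was recovered as 70%. Of 200 random lists of 40 genes, 6.5% fell outside the limits for shares, and 98.5% of lists with 85% of genes planted as marked were found. For covered bases, 3% of 200 random lists of 30 genes fell outside, and 99.5% of lists with 1000 planted bases were found. The 40 genes all lacked a DMSO interval, and their marks were drawn without regard to region. The simulated differences in covered bases were drawn independently of the strata. Real lists had as few as 8 genes without a DMSO interval, so these rates need not hold for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.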

Results

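H3K27ac, a histone mark found at active promoters and enhancers, was mapped by ChIP-seq in CD8+ T cells of C57BL/6 mice. The cells came from lymph node and spleen, were stimulated through CD3 and CD28, and were kept for 48 h with EnPGC-1 or with the vehicle DMSO. The labels class EnPGC-1 among PIPs, and the title of the series ties the work to mitochondrial biogenesis, the process that the coactivator PGC-1 is known to drive. The question was how acetylation across the genome differed with the compound. The 8 samples formed 5 groups: 2 H3K27ac samples per treatment, 2 IgG samples from DMSO-treated cells, and 1 input per treatment. The values used here were 2 peak lists, 1 per treatment, on mm10. No spread between replicates could therefore be measured, and no test between treatments was made. Bracketed ranges are 95% exact binomial intervals and cover counting error only, and the sequencing depth of each sample is unknown here.

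Far more of the genome was listed as acetylated in EnPGC-1-treated cells than in DMSO-treated cells. The EnPGC-1 list held 253423 distinct intervals covering 165 Mb, and the DMSO list 81522 intervals covering 41.3 Mb. The ratios were 3.11 for intervals and 4.00 for covered bases. Every chromosome showed the excess, with ratios of covered bases from 3.79 on chromosome 15 to 4.28 on chromosome 3. Of 2620 bins of 1 Mb, 2554 had more covered bases in the EnPGC-1 list and 0 had more in the DMSO list. The excess was slightly larger in gene-poor than in gene-rich bins, with ratios from 4.66 down to 3.83. EnPGC-1 intervals were also wider, with a median of 499 bp against 431 bp, and 20.7% of them held more than 1 summit against 3.42% in the DMSO list. When only the 81522 highest-scoring EnPGC-1 intervals were kept, they still covered 1.65 times as many bases as the DMSO list. Among equal scores at the cut, the wider intervals were kept. The number of intervals depends on depth and on the calling threshold, and neither can be matched between the lists.

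**Figure D1:**
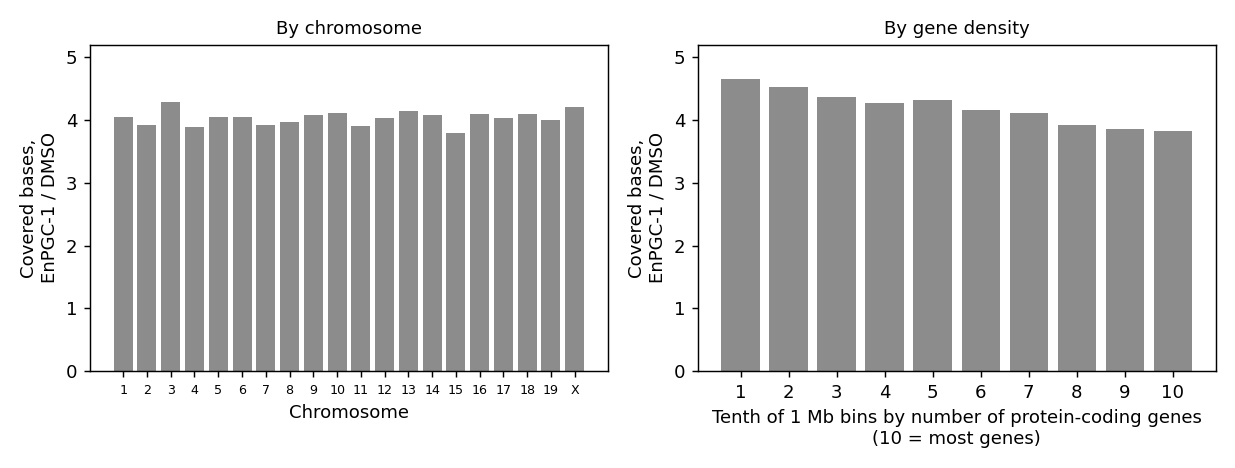
Bars give the bases covered by EnPGC-1 intervals divided by those covered by DMSO intervals, on the left for each of 20 chromosomes and on the right for 1 Mb bins grouped by their number of protein-coding genes, from fewest to most. The ratio runs from 3.79 to 4.28 between chromosomes and falls from 4.66 to 3.83 with gene density.

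Most DMSO intervals lay in regions that the EnPGC-1 list also held. Of the DMSO intervals, 60081 overlapped an EnPGC-1 interval by at least 1 bp (73.7%, 73.4 to 74.0), against 11.8% after random placement within chromosomes and 25.6% after shifts of 10 to 50 kb. Of the EnPGC-1 intervals, 58614 overlapped a DMSO interval (23.1%, 23.0 to 23.3), against 3.96% at random and 9.19% after the shifts. That left 21441 intervals in the DMSO list alone and 194809 in the EnPGC-1 list alone. With equal numbers of highest-scoring intervals the overlap was lower, at 31.4% of DMSO and 29.0% of EnPGC-1 intervals. Shared intervals lay near genes more often than unshared ones. An end of a protein-coding gene lay within 1 kb of 15.4% (15.1 to 15.7) of shared EnPGC-1 intervals and of 8.65% (8.53 to 8.78) of EnPGC-1-only intervals. The values for the DMSO list were 14.0% (13.7 to 14.3) and 9.17% (8.79 to 9.57), and random placement gave 3.80% to 4.59% over these sets. Of EnPGC-1-only intervals, 47.8% lay elsewhere within a gene and 43.6% lay outside genes.

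Acetylation at gene ends was listed for 72.0% of the 21883 protein-coding genes in EnPGC-1-treated cells and for 41.1% in DMSO-treated cells. Random placement gave 40.1% and 14.8%. Both lists marked 8524 genes, the EnPGC-1 list alone 7229, the DMSO list alone 474, and neither list 5656. Among genes without a DMSO interval, 56.1% (55.2 to 57.0) had one in the EnPGC-1 list. This excess of EnPGC-1-only genes ended when the lists were equal in number: 3342 genes were then marked in the EnPGC-1 list alone and 3572 in the DMSO list alone. That setting drops EnPGC-1 intervals with scores below 4.21 but no DMSO interval, and ties at that score were taken from the widest down. With each list cut at its own median score, the numbers were 6619 and 1509. Of the T cell genes, the coreceptor gene Cd8a, the kinase gene Lck and the cytokine gene Ifng were among 39 marked in the EnPGC-1 list alone, a share that was ordinary among random lists. The costimulatory receptor gene Icos, the survival gene Bcl2 and Il12rb2 were the 3 marked in the DMSO list alone. The CD45 gene Ptprc and the IL-2 receptor gene Il2ra had 0 covered bases within 5 kb of the gene end used, in both lists. Apart from Il12rb2, these 7 genes of the fixed lists were singled out after their values were seen.

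Genes of mitochondrial biogenesis and respiration were marked more often in the EnPGC-1 list. Pooled over 5 mitochondrial lists, 105 of 223 genes (47.1%, 40.4 to 53.9) had a gene-end interval in the DMSO list and 188 (84.3%, 78.9 to 88.8) in the EnPGC-1 list. Of the 118 genes without a DMSO interval, 91 (77.1%, 68.5 to 84.3) had an EnPGC-1 interval. The same share was 17 of 22 for the PGC-1 network, 29 of 39 for nuclear genes of oxidative phosphorylation, 20 of 25 for fatty acid oxidation, 8 of 12 for the TCA cycle and 17 of 20 for mitochondrial dynamics, import and quality control. Against 10000 random lists of genes without a DMSO interval, these shares stood at percentiles 97.9, 98.9, 99.2, 75.5 and 99.6. Without receptor genes in the random lists they stood at 93.0, 94.3, 97.2, 61.2 and 98.4, and the pooled share at 99.965. Among all protein-coding genes without a DMSO interval the share was 56.1%, and 62.0% with receptor genes left out. Within the PGC-1 network, Tfam, which encodes the mitochondrial transcription factor A, and Polrmt, which encodes the mitochondrial RNA polymerase, were marked in the EnPGC-1 list alone. So were Ndufs7, a subunit gene of complex I, and the fatty acid oxidation gene Eci1. Within 5 kb the DMSO list still covered 2105 bases at Polrmt, 1415 at Ndufs7 and 772 at Eci1. The median over all genes was 359. In the DMSO list alone were Cox7c, Cycs, Ndufa4 and Ndufs6 of the respiratory chain, the carnitine carrier gene Slc25a20, and Dnm1l, Mfn2 and Tomm22. With equal numbers of intervals, 46 mitochondrial genes were marked in the EnPGC-1 list alone and 48 in the DMSO list alone, and the pooled share stood at percentile 99.9. That percentile counts gains only. In all, 103 of the 223 genes were then marked in the EnPGC-1 list and 105 in the DMSO list, so it shows no net rise. Calculated exactly for that setting, the PGC-1 network stood at 97.47, oxidative phosphorylation at 97.96, fatty acid oxidation at 75.6, the TCA cycle at 87.9 and mitochondrial dynamics at 81.7, the last with 7 genes in the EnPGC-1 list alone and 15 in the DMSO list alone. Random lists matched on regional coverage put the pooled share at percentile 99.1, but the PGC-1 network at 88.2, oxidative phosphorylation at 59.5, fatty acid oxidation at 94.7 and mitochondrial dynamics at 93.7. Tfam, Cycs, Ndufa4, Ndufs6, Mfn2 and Tomm22 were named after their values were seen.

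**Figure D2:**
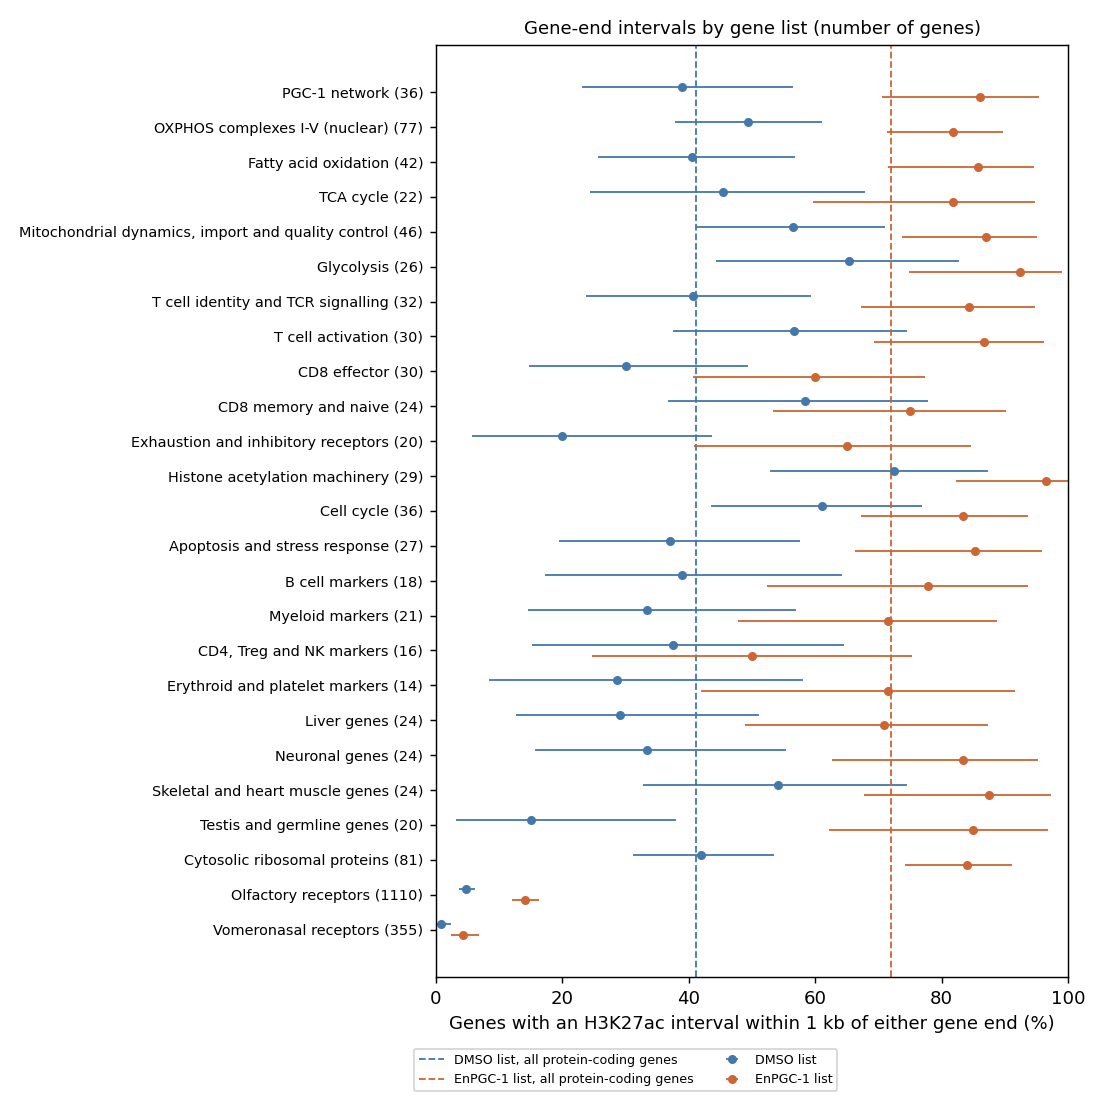
Points give the percent of each gene list's members (number in brackets) with an H3K27ac interval within 1 kb of either gene end in the DMSO and in the EnPGC-1 list, with 95% exact binomial intervals that cover counting error only. Dashed lines mark all protein-coding genes, at 41.1% and 72.0%, and every list lies higher in the EnPGC-1 list, those of other tissues included.

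Pooled T cell genes were marked about as often as random lists in both lists. Over 4 T cell lists, 53 of 116 genes (45.7%, 36.4 to 55.2) had a gene-end interval in the DMSO list and 89 (76.7%, 68.0 to 84.1) in the EnPGC-1 list. Of the 63 without a DMSO interval, 39 (61.9%, 48.8 to 73.9) had an EnPGC-1 interval, at percentile 82.5 of random lists and 48.4 without receptor genes. The share was 14 of 19 for T cell identity and receptor signalling, 10 of 13 for activation, 10 of 21 for CD8 effector genes and 5 of 10 for memory and naive genes, at percentiles 94.0, 93.1, 21.9 and 35.2. Runx3, a transcription factor gene of the CD8 lineage, and the memory regulator gene Tcf7 were marked in the EnPGC-1 list alone. Runx3 nevertheless had 1335 covered bases within 5 kb in the DMSO list, against 5942 in the EnPGC-1 list. For Tcf7 the covered bases within 5 kb were 305 in the DMSO list and 4983 in the EnPGC-1 list, but with equal numbers of intervals the difference turned to -305 bases. That setting removes EnPGC-1 intervals with scores below 4.21 and no DMSO interval, with ties at that score taken from the widest down. With each list cut at its own median score the difference was 1316 bases. Il12rb2, which encodes an IL-12 receptor chain, was marked in the DMSO list alone. Over whole genes with 10 kb on each side, the T cell lists moved apart in the DMSO list, with activation at percentile 98.2 and effector genes at 1.93 of random lists without receptor genes, and stood at 95.2 and 4.26 in the EnPGC-1 list. With equal numbers of intervals, 21 T cell genes were marked in the EnPGC-1 list alone and 22 in the DMSO list alone.

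Genes of other cell types and tissues were marked in the EnPGC-1 list as well. Over the liver, neuronal, muscle and testis lists, 31 of 92 genes (33.7%, 24.2 to 44.3) had a gene-end interval in the DMSO list and 75 (81.5%, 72.1 to 88.9) in the EnPGC-1 list. Of the 61 without a DMSO interval, 46 (75.4%, 62.7 to 85.5) had an EnPGC-1 interval, at percentile 99.9 of random lists and 99.8 with regional matching, close to the 77.1% of the mitochondrial lists and within its counting interval. The testis list had 14 of 17 at percentile 98.7, liver 11 of 17 at 75.8, neuronal genes 12 of 16 at 93.6 and muscle 9 of 11 at 95.2. Calculated exactly with equal numbers of intervals, these were 63.7, 96.8, 84.5 and 99.5. Without receptor genes in the random lists, the testis list stood at 95.85. Neurod2, a transcription factor gene of neurons, and Mylpf, a myosin light chain gene of muscle, went from 0 covered bases within 5 kb to 5052 and 5862. Those differences were 2342 and 5129 with equal numbers of intervals, and the same at or above the median score. With equal numbers of intervals, 26 genes of these lists were marked in the EnPGC-1 list alone and 12 in the DMSO list alone. Among blood cell lists, B cell markers had 8 of 11, at percentile 85.8, and myeloid markers 9 of 14, at 72.0. Erythroid and platelet markers had 6 of 10, at 58.9, and CD4, Treg and NK markers 3 of 10, at 5.67. The B cell transcription factor gene Spib had 912 covered bases in the DMSO list and 6217 in the EnPGC-1 list.

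Among the remaining lists, genes of glycolysis, histone acetylation and stress without a DMSO interval had an EnPGC-1 interval more often than random lists of such genes. Glycolysis and histone acetylation genes were also often marked in the DMSO list, in 17 of 26 and 21 of 29 genes. All 8 genes of the histone acetylation machinery without a DMSO interval had an EnPGC-1 interval, at percentile 99.5. Hdac3 and Sirt2, which encode deacetylases, were among them, whereas the acetyltransferase gene Kat6a, named after its value was seen, was marked in the DMSO list alone. Glycolysis had 8 of 9, at percentile 97.6, with the hexokinase gene Hk1 in the EnPGC-1 list alone and Pgam1 in the DMSO list alone. Apoptosis and stress response had 14 of 17 at percentile 98.5, with Ddit3 and Bak1 in the EnPGC-1 list alone. Cell cycle genes had 11 of 14 at percentile 94.995, and exhaustion and inhibitory receptor genes 9 of 16 at 50.4. Lag3 and Nr4a1, both known from exhausted T cells, were marked in the EnPGC-1 list alone. Within 5 kb, Nr4a1, Sirt2, Hk1, Hdac3 and Ddit3 had 1713, 1176, 1094, 1085 and 1070 covered bases in the DMSO list. Lag3 and Bak1 had 491 and 291. In all, 8 of 22 lists lay outside the central 95% of random lists. The count was 3 by exact calculation with equal numbers of intervals, for oxidative phosphorylation, T cell activation and muscle. The PGC-1 network sat at the limit in that setting, outside at percentile 97.68 in 1 set of random lists and inside at 97.48 in another and at 97.47 exactly. The count was also 3 with receptor genes left out of the random lists, for mitochondrial dynamics, histone acetylation and, on the low side, CD4, Treg and NK markers, and 1 with regional matching, for neuronal genes. Glycolysis, histone acetylation and stress stood at 87.6, 92.2 and 80.3 with equal numbers of intervals.

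Listed intervals covered more bases around gene ends in the EnPGC-1 list at most genes. A covered length also depends on how much was called in each list, so it is not read as a measured gain of acetylation. The median covered length within 5 kb was 359 bases in the DMSO list and 1407 in the EnPGC-1 list, and 79.1% of genes had more covered bases in the EnPGC-1 list against 5.22% in the DMSO list. The largest differences in the mitochondrial lists were 6672 bases at the acyl-CoA dehydrogenase gene Acadvl, 6553 at Ndufs7, 6126 at the mitochondrial protease gene Lonp1 and 6001 at the nuclear receptor gene Rxra. They were 5567, 4358, 6126 and 3808 with equal numbers of intervals. Sirt1 had 0 covered bases in both lists, and at Cox7c the DMSO list covered 597 bases and the EnPGC-1 list 0. Median differences were 2114 bases for the PGC-1 network and 927 for oxidative phosphorylation, at percentiles 91.8 and 2.56 of random lists matched on mean covered bases. For the T cell lists they were 1578 for identity, 1472 for activation, 752 for effector and 1371 for memory genes, at percentiles 94.0, 15.1, 77.2 and 52.3. Of the 22 lists, 0 lay outside the central 95% of these matched random lists. The mean used for matching includes the EnPGC-1 bases, so lists with large gains were compared with genes of large gains. Muscle genes had a median difference of 2694.5 bases, beside 2372.5 in matched lists, and stood at percentile 82.4. A gain shared by a list can thus be missed, and unmatched random lists put some lists outside. Oxidative phosphorylation sat at the limit: 100000 random lists put it at percentile 2.18, but it stood at 51.8 with intervals at or above the median score, 63.3 with equal numbers of intervals and 39.4 with a window of 10 kb. With lists made equal in number, the median differences were 519 bases for the PGC-1 network, 302 for oxidative phosphorylation, 84.5 for T cell identity, 102.5 for activation, 86 for effector and 0 for memory genes.

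The loci of the PGC-1 genes themselves held more intervals in the EnPGC-1 list, by about the ratio of the whole lists. Ppargc1a, the gene of PGC-1 alpha, lies on chromosome 5 from 51454249 to 52115853 (mm10). With 50 kb on each side it held 11 DMSO intervals and 32 EnPGC-1 intervals, which covered 0.638% and 2.17% of the region. This difference lay at percentile 19.6 of all protein-coding genes. Intervals within 1 kb of the gene end near 52115853 appeared in the EnPGC-1 list alone, from 52114594 to 52115354 and from 52115839 to 52116718. Just outside that window lay a DMSO interval, from 52113842 to 52114417, which overlapped an EnPGC-1 interval. Without strand, these intervals are not read as a new mark at the promoter. The highest-scoring EnPGC-1 interval of the locus, inside the gene from 51775682 to 51776013, overlapped no DMSO interval. Ppargc1b, the gene of PGC-1 beta, lies on chromosome 18 from 61291445 to 61400756. Its region held 20 DMSO and 56 EnPGC-1 intervals, which covered 5.14% and 19.8%, a difference at percentile 74.3. Both lists had intervals at the gene end near 61400756. The ratio over both loci was 2.84, and 1.26 with equal numbers of intervals.

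**Figure D3:**
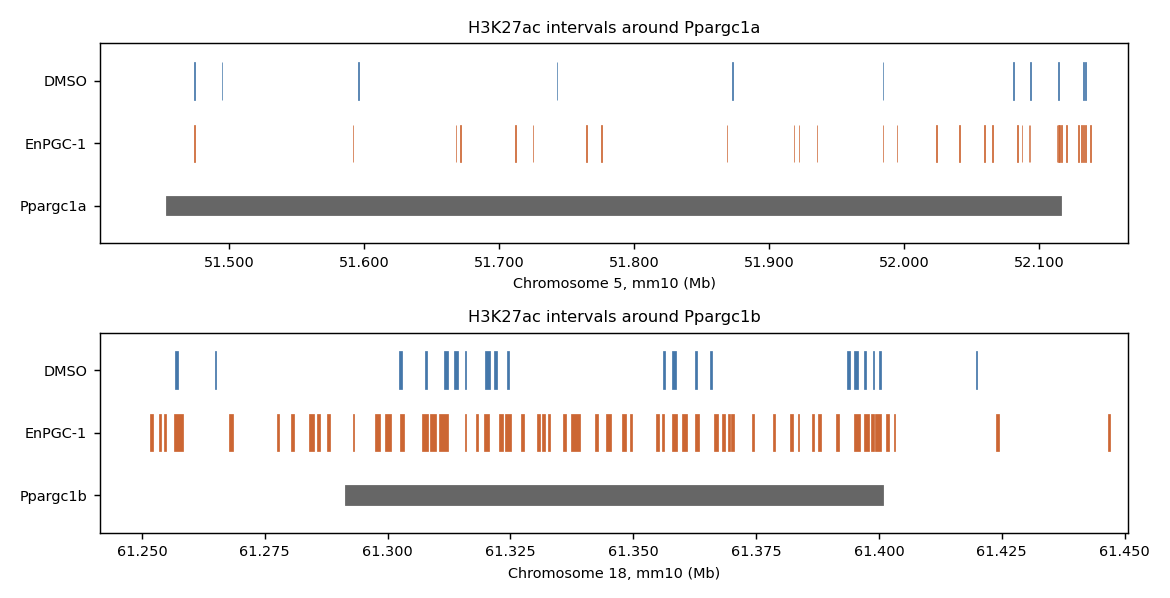
Blue bars are DMSO intervals and orange bars EnPGC-1 intervals, drawn to scale along mm10 in Mb, with the gene in grey, for Ppargc1a on chromosome 5 and Ppargc1b on chromosome 18, each with 50 kb on both sides. The Ppargc1a region holds 11 and 32 intervals, and the more densely covered Ppargc1b region 20 and 56.

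Most of the leading DMSO domains overlapped leading EnPGC-1 domains, and fewer did the other way round. After neighbouring intervals were joined, 431 of the 500 DMSO domains with most covered bases (86.2%, 82.9 to 89.1) overlapped the 500 leading EnPGC-1 domains, against 13.7% for domains placed at random. Of the 500 leading EnPGC-1 domains, 264 (52.8%, 48.3 to 57.2) overlapped leading DMSO domains, against 9.97% at random, and their median span was 337 kb against 94.4 kb in the DMSO list. The DMSO share was 65.4% with equal numbers of intervals. The leading DMSO domain lay on chromosome 8 from 120128932 to 120586217, over Gse1, with 72.6 kb covered. The leading EnPGC-1 domain, from 119339623 to 122927432 on the same chromosome, contained it and had 1626 kb covered over 63 protein-coding genes, with an end of Foxl1 nearest to its centre. Next in the DMSO list, named by the gene end nearest to the centre, came domains at Chd5 on chromosome 4, Sbno2 on chromosome 10, Kif26a on chromosome 12 and Lmf1 on chromosome 17. Next in the EnPGC-1 list came domains at Ajap1 on chromosome 4, Onecut3 on chromosome 10 and Igsf21 on chromosome 4. The third EnPGC-1 domain, with 115 protein-coding genes, also spanned the Sbno2 domain.

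The 10 highest-scoring intervals found in each list alone had nearest genes that belong to none of the fixed lists, and those of the EnPGC-1 list lay partly in clusters. The score is the authors' value for each interval and ranks intervals only within its own list. Leading the EnPGC-1-only intervals was chromosome 2 from 98666615 to 98667259, more than 1000 kb from the nearest protein-coding gene, Lrrc4c. Of the next intervals, 4 lay on chromosome 11 between 3130757 and 3189503, of which 3 lay in Sfi1 and 1 in the neighbouring pseudogene Pisd-ps1, and 2 more on chromosome 9 between 3024060 and 3025958. Repeated sequence under these intervals was not checked. Other leading EnPGC-1-only intervals were near Gm17019 on chromosome 5, Gm32719 on chromosome 12 and Pisd on chromosome 5. The leading DMSO-only intervals were on chromosome 1 from 84956887 to 84957256, near Slc16a14, and from 88283420 to 88283734, near Hjurp. Others lay within Gm9758, Nup210l, Dpp6, Prr5l and the transketolase gene Tkt.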

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

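The count of deposited entries, the random lists without receptor genes or with regional matching, whole genes, the exact percentiles and the draw of 100000 lists were chosen after the results were seen. No paired analysis was possible because the values used hold 1 list per treatment, and for the same reason a fit with the replicate numbers as a block and leaving out each replicate in turn were not run. Depth per sample is unknown, so no result was corrected for it. The EnPGC-1 list covered more bases in each setting in which this ratio was computed, and its shared intervals lay nearer to gene ends than its unshared ones throughout. In contrast, the excess of EnPGC-1-only genes over DMSO-only genes ended with equal numbers of intervals. For all values, the cause was not tested beyond what each setting removes by construction.

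With intervals at or above their own list's median score, the ratios were 2.599 for intervals and 3.66 for covered bases, and overlap was 45.5% of DMSO and 17.03% of EnPGC-1 intervals. Gene ends took 9.71% of EnPGC-1-only and 17.3% of shared EnPGC-1 intervals, DMSO-only genes numbered 1509, and domain overlap was 65.6%. Gene lists outside the limits numbered 5 for shares and 2 for covered bases. With equal numbers of highest-scoring intervals, the ratios were 1 by construction and 1.65, overlap was 31.4% and 29.0%, and gene ends took 9.40% and 18.4%. Genes marked in 1 list alone numbered 3342 for EnPGC-1 and 3572 for DMSO, gene lists outside the limits 4 (3 by exact percentile) and 1, domain overlap was 65.4%, and the ratio at the PGC-1 loci was 1.26. With intervals within 1000 bp merged, the ratios were 2.54 and 4.40, overlap was 74.4% and 26.1%, and gene ends took 7.97% and 19.1%. With intervals under 500 bp left out, the ratios were 4.26 and 5.40, overlap 69.96% and 16.4%, gene ends 12.46% and 19.8%, lists outside for shares 4, and domain overlap 73.2%. Without chromosome X, the ratio of covered bases was 4.00, and lists outside numbered 5 and 1.

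Requiring 50% of an interval to be covered gave overlaps of 63.9% and 13.5% and gene-end shares of 9.78% and 13.1%. Counting intervals within 1000 bp as shared gave 84.7% and 33.8%, and 7.97% and 14.6%. Windows of 500 bp gave gene-end shares of 6.28% and 12.2% with 4 lists outside, and windows of 2500 bp 14.9% and 22.9% with 4. Unmatched random lists put 4 lists outside for covered bases, whole genes with 10 kb put 1, and 100000 random lists put 1, oxidative phosphorylation. Random lists without receptor genes left 3 lists outside for shares, and regional matching 1. Domains joined within 5000 bp overlapped in 60.8%. Counting deposited entries gave a ratio of 3.90. Of single named genes' differences in covered bases, 285 stayed within 1.5 times and 122 moved, and of list medians 71 and 61. Of the lists' shares, 131 stayed within counting error and 23 moved. No list median changed sign, but 6 of 22 fell to 0 with equal numbers of intervals. Equal numbers of intervals turned 3 named genes, E2f1, Il2rb and Tcf7, and windows of 10 kb turned 7, among them Slc25a20, Dnm1l, Cs and Pgam1. Intervals at or above the median score turned 3, leaving out narrow intervals 2 and merging 1.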

Other observations

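Of the tests in this part, only the overlap of the highest-scoring EnPGC-1 intervals and the percentile of the PGC-1 network, with its settings of score, width, window and chromosome X, were set before the data were examined, and all others were chosen after the results were seen. Receptor families of sensory neurons were marked less often than genes at large in both lists. Of 1110 olfactory receptor genes, 53 (4.77%, 3.597 to 6.199) had a gene-end interval in the DMSO list and 156 (14.1%, 12.1 to 16.2) in the EnPGC-1 list. Of 355 vomeronasal receptor genes, 3 (0.845%, 0.175 to 2.45) had one in the DMSO list and 15 (4.23%, 2.38 to 6.87) in the EnPGC-1 list. Genes of cytosolic ribosomal proteins, which most cells express strongly, had 34 of 81 in the DMSO list and 36 of the other 47 (76.6%) in the EnPGC-1 list. The 34 were 42.0%, against 41.1% of all protein-coding genes. Gene-end intervals of the DMSO list thus did not set these strongly expressed genes apart. In the EnPGC-1 list 68 of 81 (84.0%) were marked, against 72.0% of all protein-coding genes and 76.4% with receptor genes left out. The lists of other tissues reached 81.5%. The share of 36 of 47 stood at percentile 99.7 of random lists, 98.2 without receptor genes and 67.0 with regional matching. Across 1 Mb bins, which are not independent replicates, covered bases had a Spearman's rho of 0.97 between the lists, and of 0.702 (DMSO) and 0.709 (EnPGC-1) with the number of genes. A test that read the first value as a rise along a shared landscape was dropped, because more sensitive calling would give the same. Over whole genes with 10 kb on each side, muscle and glycolysis genes were the most densely covered of the 22 lists, with medians of 6.46% and 6.34% in the DMSO list and 30.8% and 25.2% in the EnPGC-1 list. CD8 effector genes had the lowest, 0.866% and 4.93%, against 2.199% and 9.34% in random lists.

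The highest scores of both lists gathered at a few loci. Of the 20 highest-scoring intervals, 10 in the DMSO list and 11 in the EnPGC-1 list lay on chromosome 11 between 3100000 and 3200000, over Sfi1 and the pseudogene Pisd-ps1. A further 4 and 2 lay on chromosome 17 between 39843004 and 39848800, at the ribosomal RNA pseudogene Rn18s-rs5. Of these 20, 20 and 17 overlapped an interval of the other list. Repeats under these intervals were not checked, so they are not read as acetylation of the genes named.

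The EnPGC-1 list held 3.11 times as many intervals as the DMSO list, and if more sensitive calling of 1 landscape were the cause, at least 80% of the top EnPGC-1 intervals by score should overlap a DMSO interval, and under 50% was set to count against it. The value was 32.7% (32.1 to 33.3), past the limit set against it, but that limit took for granted that high scores mark intervals found again. Within the EnPGC-1 list, overlap did rise with score. It was 23.1% over all EnPGC-1 intervals and 16.4% (15.9 to 16.9) in the 25342 of lowest score. Those were also narrower, with a median of 403 bp against 694 bp in the top EnPGC-1 intervals. Equal scores were ordered by width, widest first, so part of that difference is built in and score is not separated from width. The top DMSO intervals by score overlapped the larger EnPGC-1 list in only 74.8% (73.8 to 75.7), against 73.7% of all DMSO intervals. What the limit took for granted thus held at most in part in the EnPGC-1 list and hardly for the top DMSO intervals. The value of 32.7% therefore does not decide, and depth, enrichment and threshold stay open. Gains at the PGC-1 network reached percentile 97.9, past its planned limit, and 99.4 without intervals under 500 bp, but 87.8 at or above the median score, 96.7 without chromosome X, and 96.9 and 91.8 with windows of 500 and 2500 bp. It was also 88.2 with regional matching and 93.0 without receptor genes. Gains were not confined to the network, where the share was 77.3%. Among all genes without a DMSO interval it was 56.1%, and in the lists of other tissues 75.4%. Whether the network gained beyond a genome-wide rise cannot be told from 1 list per treatment.

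Pooled T cell genes carried gene-end intervals about as often as genes at large, although the cells were T cells. Their share stood at percentile 50.7 in the EnPGC-1 list and 65.2 in the DMSO list of random lists without receptor genes. A test of regional background as the cause was dropped because it used this same share, which only restates the pattern. Counting both gene ends could also dilute promoters: over whole genes with 10 kb on each side, the percentiles were 92.4 and 90.3, between the limits set for and against it, and activation and effector genes went opposite ways, so this stays open. Input and IgG values were not analysed here, and no biological explanation was tested for this pattern.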
